A study of Mus musculus with 9 samples.

How the data were processed

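RNA bound to tagged ribosomes was measured in 9 mouse libraries by RNA sequencing. In RiboTag mice, Cre recombinase switches on an HA-tagged copy of the ribosomal protein Rpl22 in a chosen cell type, and an antibody to HA then pulls down the ribosomes of that cell type with their RNA. Per the labels' protocols, 50 to 100 mg of white adipose tissue was homogenised for each capture, and cDNA was made from 2 to 5 ng of RNA with a low-input kit that copies polyadenylated RNA, followed by tagmentation, which does not mark the strand. The Cre driver was Pdgfb-iCreERT2, which acts in endothelial cells. Per the labels, 4 libraries (WT) carried an intact endothelial Mfn2 gene and 5 libraries (KO) came from mice lacking endothelial Mfn2. The labels call the replicates biological without naming the animals, so p-values measure the spread between these libraries.

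The authors deposited values in CPM, each gene's read count scaled to a common library total, for 11802 genes, per the labels and the values themselves. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0, edgeR 3.32.0, R 4.0.2 and the builds GRCm38 and mm10, without giving the role of each. The read counter, its strand setting and the gene annotation are not given in the sources used here. Gene symbols, classes and coordinates were taken from GENCODE M21 (GRCm38) by gene identifier, which matched 11787 genes and left 15 without a symbol.

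The deposited CPM in each library were whole multiples of a single step, so whole reads could be recovered. Across libraries, at least 99.98% of the nonzero values came out whole within 0.1 read. The columns summed to between 946406 and 990292, so the CPM carried no further scaling factor. Listed reads numbered 2200640, 2501048, 1857195 and 1034753 in WT replicates 1 to 4 and 3233717, 2061621, 2695405, 1615968 and 3829356 in KO replicates 1 to 5. A share of reads in a single library is given with its 95% Wilson interval, which covers counting error only, since reads without molecular identifiers are not independent molecules.

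The test for single genes was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(CPM + 1), and Benjamini-Hochberg adjusted p under 0.05 counted as a call. Fold changes on this scale understate the change of genes with low CPM. A filter at a mean CPM of 1 removed 0 genes, because the lowest mean of a listed gene was 1.77 CPM. In these values the median of all genes was shifted between the groups, so each result is also given relative to the library median: each library's median log2 value was subtracted before the same limma test. Values described as relative come from that fit. Single values were compared with exact two-sided permutation tests over the 126 splits of the 9 libraries into 4 and 5, whose smallest possible p is 0.00794.

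Before the data were examined, 60 gene lists for cell types, complexes and pathways were written, and 54 of them had at least 5 measured genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 54 lists. Camera with an estimated correlation, fry and exact permutation of each list's mean per library were run beside it. For each list, the number of called members is given over all genes tested and adjusted over the list alone.

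The genes named in the text were chosen by a rule also fixed before the data were examined. They are Mfn2, then the 10 genes higher and the 10 genes lower with the largest log2 fold change. Those had to have an adjusted p under 0.05, a mean CPM of at least 5, no overlap between the groups, and a symbol other than a predicted-gene name. For each list described, up to 4 called members with the smallest p were added, or up to 2 members with the highest mean CPM where no member was called. Only 2 genes met the rule among those lower. The 13 genes called relative to the library median were named after their values were seen.

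The alternatives were pseudocounts of 0.5 and 5, a mean CPM of at least 5, no filter, quantile normalisation, median centring, limma without trend, array weights, the replicate number as a block, the adipocyte list mean as a covariate, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Rescaling without the mitochondrial rRNAs, covariates for the mitochondrial rRNA share and the endothelial list mean, and leaving out WT replicate 4 with KO replicate 5 were added after seeing the data. The tests were checked on simulated data, with 100 genes changed by each fold among 11800 genes in 4 against 5 libraries. In that simulation of KO versus WT, limma recovered 8% of the genes changed 2-fold and 49% of those changed 4-fold with 5 false calls. On the same simulated reads edgeR recovered 7% and 56% with 4 false calls, and DESeq2 recovered 12% and 58% with 13 false calls. The simulated list test called 1 of 54 lists, the raised one, which was the endothelial list. Simulated genes were drawn independently, so this could not show false calls from genes that vary together. In the real data the estimated correlation of that list was 0.74, against the preset 0.01.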

Results

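The series profiled ribosome-bound RNA from the endothelial cells of mouse white adipose tissue, to compare endothelium with and without Mfn2. Mfn2 encodes mitofusin 2, an outer mitochondrial membrane protein needed for mitochondrial fusion. There were 4 libraries labelled WT and 5 labelled KO, with 1034753 reads in WT replicate 4 at the lowest and 3829356 reads in KO replicate 5 at the highest. The labels gave no batch or date. Correlations of log2 values between replicates of a group ranged from 0.745 to 0.880 across genes, which are not independent replicates, and no library was a copy of another.

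Mfn2 RNA was not lower in the libraries labelled KO. Mfn2 (ENSMUSG00000029020; GRCm38 chromosome 4, 147873599 to 147904704, minus strand) was at 36.1 ± 15.0 CPM (SD, n = 4) in the libraries labelled WT and 66.7 ± 37.0 CPM (SD, n = 5) in those labelled KO. The log2 fold change was 0.81 (SE 0.446, limma adjusted p = 0.131), and relative to the library median it was −0.16 (SE 0.365, adjusted p = 0.898), with a 95% interval from −0.92 to 0.60. An exact two-sided permutation test gave p = 0.135 for CPM and p = 0.659 for the relative values. Mfn2 had 45, 141, 58 and 40 reads in WT replicates 1 to 4 and 427, 74, 158, 112 and 179 reads in KO replicates 1 to 5. The level of the targeted gene therefore did not separate the labels, and every direction below rests on the labels alone. The labels do not say which exons were deleted, and reads outside the deleted part do not show directly whether that part was lost. Whether the deletion changes the level of the remaining transcript was not tested. Mfn2 RNA from other cell types was not told apart either, so the level cannot check deletion within endothelial cells. With the adipocyte list mean as a covariate the log2 fold change in the deposited CPM was 0.13 (limma adjusted p = 0.849). The 16 measured genes near Mfn2 on chromosome 4 had a relative median of 0.01, and 1 of them was called higher (0 adjusted over the list alone; camera adjusted p = 0.697).

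Mitochondrial ribosomal RNA took a larger share of the reads in 3 of the 4 libraries labelled WT. Together mt-Rnr1 and mt-Rnr2, the ribosomal RNAs of the mitochondrial genome, made up 64.8% (95% Wilson interval 64.7 to 64.9), 47.5% (47.4 to 47.6) and 48.3% (48.2 to 48.4) of reads in WT replicates 1 to 3. The share was 13.9% (13.8 to 13.9) in WT replicate 4, and in the libraries labelled KO it ran from 12.8% (12.7 to 12.8) to 25.2% (25.1 to 25.3). The group values were 43.6% ± 21.4 (SD, n = 4) and 18.2% ± 4.76 (SD, n = 5), with an exact permutation p = 0.0476, or 0.1 adjusted over 9 RNA classes. Nuclear protein-coding genes took 36.5% ± 14.7 of reads in WT (n = 4) and 65.2% ± 7.88 in KO (n = 5; exact permutation p = 0.0159, adjusted 0.1). Malat1, an abundant nuclear noncoding RNA, took 18.4% of reads in WT replicate 4 and between 1.21% and 9.11% in the other libraries (exact permutation p = 0.278 between groups of 4 and 5). Sets that would separate the high from the low mitochondrial rRNA shares held 1 WT library on the low side and no KO library on the high side, so no replicated comparison within such sets was possible.

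**Figure D1:**
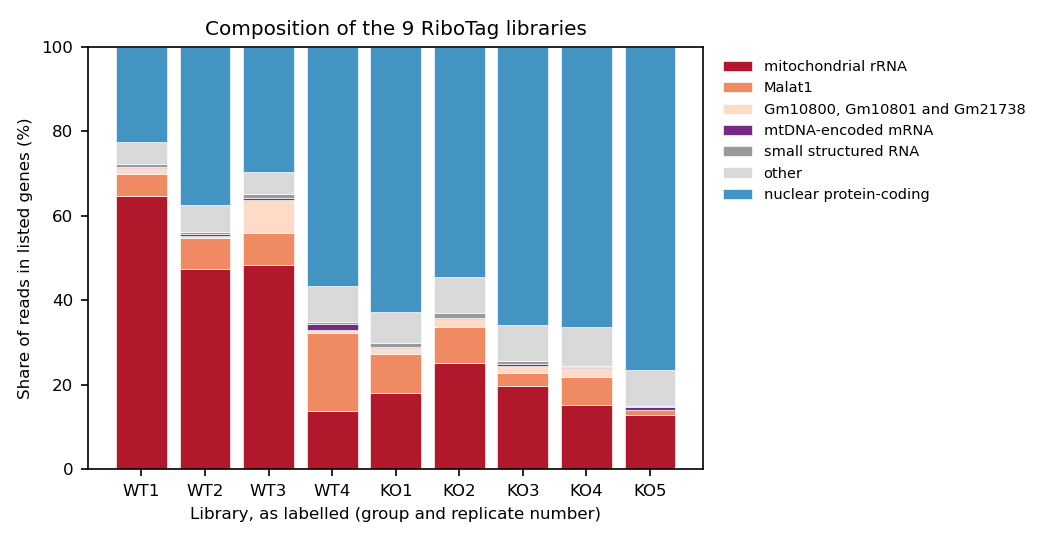
Share of the reads in listed genes (%, vertical axis) taken by 7 RNA classes in each of the 9 libraries (horizontal axis), 1 stacked bar per library. Mitochondrial rRNA made up 64.8%, 47.5% and 48.3% in WT replicates 1 to 3, 13.9% in WT replicate 4 and at most 25.2% in the libraries labelled KO.

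In the deposited CPM, nearly all genes lay higher in the libraries labelled KO. Of 11802 genes, 3780 (32.0%) were called higher and 24 lower (limma), 94.6% had a log2 fold change above 0, and the median log2 fold change was 1.10. The library medians differed by 0.98 on the log2 scale (exact permutation p = 0.00794, all 5 KO medians above all 4 WT medians). WT and KO values did not overlap in 2207 genes (18.7%, against 1.59% by chance). Relative to the library medians 4 genes were called higher and 9 lower, with 1378 genes at an unadjusted p under 0.05 (707 higher, 671 lower). On the recovered reads edgeR called 1 gene higher and 4 lower, and DESeq2 called 31 higher and 124 lower, with no adjusted p for 7793 genes. The changes below are therefore given relative to this shift. Counts of list members called higher in the deposited CPM carry the shift and stand against the 32.0% of all genes. Relative medians of lists stand against a relative median of 0.12 over all genes, of which 57.9% lay above 0.

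Depp1, Ddit4, Rhob and Selenok were the 4 genes that rose relative to the library medians. Depp1, a FOXO-responsive gene linked to autophagy (chromosome 6, 116650609 to 116652794), was at 17.6 ± 7.60 CPM in WT (SD, n = 4) and 168 ± 65.3 CPM in KO (SD, n = 5), a relative log2 fold change of 2.26 (SE 0.331, limma adjusted p = 0.00944). Ddit4, which encodes the mTORC1 inhibitor REDD1 (chromosome 10, 59949669 to 59951834), went from 32.4 ± 14.6 to 245 ± 69.1 CPM, a relative change of 1.99 (SE 0.357, adjusted p = 0.0403). The small GTPase gene Rhob (chromosome 12, 8497661 to 8500009) went from 38.3 ± 13.2 to 251 ± 71.6 CPM, a relative change of 1.72 (SE 0.296, adjusted p = 0.0290). Selenok, a selenoprotein gene of the endoplasmic reticulum (chromosome 14, 29968308 to 29975662), went from 60.8 ± 37.9 to 316 ± 86.3 CPM, a relative change of 1.56 (SE 0.303, adjusted p = 0.0491). For each of these 4 genes all 5 KO libraries lay above all 4 WT libraries in CPM. Depp1 overlaps Rassf4 on the other strand, which was at 11.6 CPM in WT and 32.2 CPM in KO, with a relative change of 0.62 (adjusted p = 0.602), and without strand the reads of the pair cannot be told apart. Depp1 lost its call without WT replicate 1 (adjusted p = 0.0708) or KO replicate 3 (0.0511). Of the 9 settings that each left out 1 library, Ddit4 kept its call in 3, Rhob in 4 and Selenok in 2, and the direction held in all 9 for each. EdgeR called Depp1 (adjusted p = 0.0318) and not Ddit4 (0.0769), Rhob (0.0575) or Selenok (0.0769), and DESeq2 called all 4. None of the 4 was called in limma without trend (adjusted p = 0.251 to 0.336), with the mitochondrial rRNA share as a covariate (0.0504 to 0.255) or with the endothelial list mean as a covariate (0.221 to 0.454). Their changes in that order were 2.29, 2.39, 2.00 and 1.39 with the rRNA covariate and 1.95, 1.73, 1.51 and 1.22 with the endothelial one. A pseudocount of 0.5 ended the calls of Ddit4 and Selenok (limma adjusted p = 0.0562 for each). The adipocyte covariate ended those of Ddit4 (0.0580), Rhob (0.0549) and Selenok (0.148). Selenok also lost its call at a mean CPM of at least 5 (0.0573) and with the mitochondrial rRNAs left out (0.0556). Depp1 kept its call in these settings.

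Rasd1, a Ras-like GTPase gene induced by dexamethasone, was the only nuclear protein-coding gene that limma called lower relative to the library medians. It was at 46.6 ± 7.04 CPM in WT (SD, n = 4) and 13.3 ± 5.13 CPM in KO (SD, n = 5), and it fell in the deposited values too (log2 fold change −1.82, SE 0.483, limma adjusted p = 0.00994). Its relative change was −2.80 (SE 0.421, adjusted p = 0.00944), and all 5 KO libraries lay below all 4 WT libraries in CPM (chromosome 11, 59963181 to 59964944). The RNase P RNA-like gene Rprl3 (chromosome 8, 3803069 to 3803358) was at 24.3 ± 30.9 CPM in WT and 0.42 ± 0.665 CPM in KO, a relative change of −4.58 (SE 0.754, adjusted p = 0.0218). Rprl3 was at 0 in 3 of the 5 KO libraries, so the size of this change rests on the pseudocount and gives no bound. WT replicate 1 alone held 70.7 CPM of Rprl3, whose relative call held in 6 of the 9 settings that each left out 1 library. Rasd1 lost its call without WT replicate 1 (adjusted p = 0.0778) or WT replicate 3 (0.0555), in limma without trend (0.204) and with the mitochondrial rRNA (0.152), endothelial (0.234) or adipocyte (0.0549) covariate, and edgeR and DESeq2 called it. In the settings that lost the call, its relative change ran from −2.80 (limma without trend) to −2.20 (mitochondrial rRNA covariate). Unannotated transcripts Gm47445, inside Dse, and A130071D04Rik, inside Ptprc, also fell (relative changes −3.25 and −3.43, adjusted p = 0.0488 and 0.0444). Each kept its call in 4 of the 9 settings that left out 1 library, and their reads cannot be separated from those of the host gene.

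**Figure D2:**
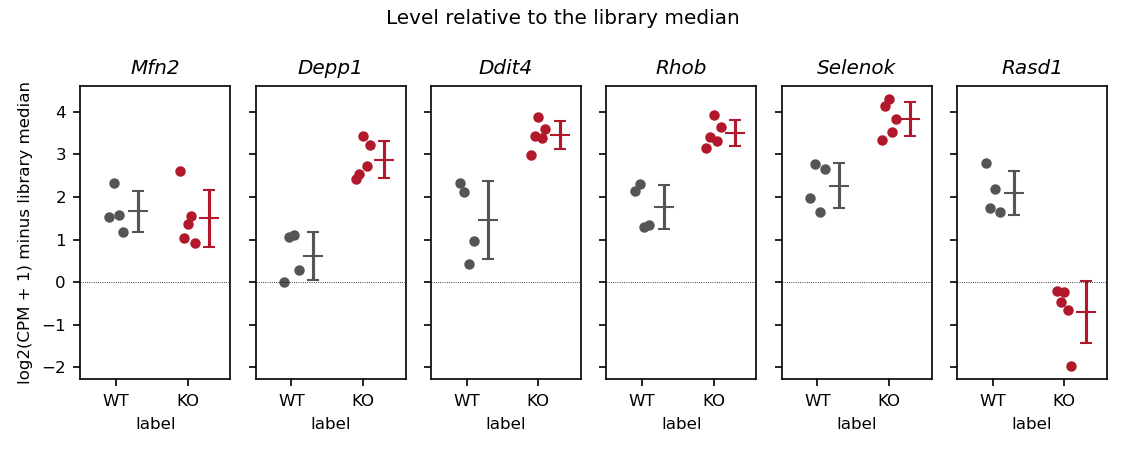
Level of 6 genes as log2(CPM + 1) minus the library median (vertical axis) in the libraries labelled WT (grey, n = 4) and KO (red, n = 5). Points are libraries and bars give the mean ± SD. The groups overlap for Mfn2 and are apart for Depp1, Ddit4, Rhob, Selenok and Rasd1.

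Genes encoded by the mitochondrial genome were lower in the libraries labelled KO relative to the library medians, while their share of the reads was not shown to differ. They took 0.642% ± 0.607 of reads in WT (SD, n = 4) and 0.451% ± 0.147 in KO (SD, n = 5; exact permutation p = 0.722), and WT replicates 1 and 2, at 0.294% and 0.284%, lay below every KO library (0.347% to 0.702%). All 13 protein-coding genes of the mitochondrial genome had a relative log2 fold change below 0 (median −1.65), 3 of them fell over all genes tested and 12 fell adjusted over the list alone. The list was called lower by camera (adjusted p = 1.69e-19), and the call was lost with an estimated correlation (adjusted p = 0.774). The 3 were the cytochrome c oxidase subunit genes mt-Co1 (926 ± 828 CPM in WT, n = 4, and 394 ± 114 CPM in KO, n = 5; relative change −1.88, SE 0.356, adjusted p = 0.0488), mt-Co2 (−2.42, SE 0.477, adjusted p = 0.0491) and mt-Co3 (−1.85, SE 0.360, adjusted p = 0.0491). In the deposited CPM only mt-Co2 was called (log2 fold change −1.45, adjusted p = 0.0248). Whether RNA of the mitochondrial genome was bound to the tagged ribosomes was not tested. These levels therefore do not measure its expression within endothelial cells. WT replicate 4 held the highest value of each of the 3, and without it the list's relative median was −1.37. The mt-Co2 gene lost its call in the deposited CPM without WT replicate 4 (adjusted p = 0.125), WT replicate 3 (0.0761) or KO replicate 3 (0.0569), and of the 9 settings that each left out 1 library the relative calls of mt-Co1, mt-Co2 and mt-Co3 held in 2, 3 and 2. All 3 relative calls were also lost in limma without trend and with the endothelial or mitochondrial rRNA covariate, where the change of mt-Co1 was −1.88, −1.56 and −2.29. EdgeR and quantile normalisation called mt-Co3 and not mt-Co1 (adjusted p = 0.0573 and 0.0674) or mt-Co2 (0.0575 and 0.0525), and DESeq2 called all 3 (4.27e-05 for each). The chromosome 1 pseudogenes Gm28661 and Gm29216 also fell (relative changes −2.29 and −2.21, adjusted p = 0.0491 and 0.0488). Gm28661 matches mt-Co2 over 681 bases at 100% identity and Gm29216 matches mt-Co1 over 483 bases at 99.8%. A further copy, Gm28437, matches mt-Co3 over 783 bases at 100%. Reads from the matching stretches could belong to either copy. Gm28661 and Gm29216 kept their relative calls in 3 and 2 of the 9 settings that each left out 1 library.

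Endothelial genes lay higher in the libraries labelled KO, beyond the shift of all genes in the list test. Of 24 measured genes of endothelial identity, 20 were called higher in the deposited CPM (22 adjusted over the list alone) and their relative median was 0.44. Kdr, the main VEGF receptor, went from 360 ± 202 CPM (SD, n = 4) to 1187 ± 505 CPM (SD, n = 5), with a log2 fold change of 1.75 (limma adjusted p = 0.00753) and a relative change of 0.77 (adjusted p = 0.326). Clec14a, Fli1 and Cd93 had relative changes of 1.11, 0.98 and 0.70. Of 14 capillary genes, 12 were called higher (12 adjusted over the list alone, 4 of them also in the relative values), with a relative median of 0.59. Sgk1, Timp4, Btnl9 and Rgcc had relative changes of 1.32, 1.50, 0.97 and 1.12, none of them called by limma over all genes (adjusted p = 0.131 to 0.234), while DESeq2 called Sgk1 (0.0207) and Rgcc (0.0414). Of 16 arterial genes, 9 were called higher (10 adjusted over the list alone), among them Sema3g (84.2 ± 46.4 CPM in WT, n = 4, and 390 ± 228 CPM in KO, n = 5), Efnb2, Mecom and Sox17. Camera gave adjusted p = 2.58e-05 for the endothelial, 3.06e-05 for the capillary and 0.0374 for the arterial list, and none was called with an estimated correlation (adjusted p = 0.931 for each) or with the mitochondrial rRNA share as a covariate (0.302, 0.153 and 0.753). The arterial call was also lost with median centring (adjusted p = 0.0554), with the replicate number as a block (0.0770) and without WT replicate 1 (0.162), WT replicate 2 (0.118) or KO replicate 3, 4 or 5 (0.0893 to 0.0908).

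Adipocyte and fibroblast genes lay lower in the libraries labelled KO relative to the library medians. Of 24 measured adipocyte genes, 4 were called higher in the deposited CPM (Retn, Pnpla2, Cfd and Car3; 0 adjusted over the list alone), 19 had a relative change below 0, and the relative median was −0.42. Retn went from 7.19 ± 2.44 to 24.0 ± 9.64 CPM (n = 4 and 5; relative change 0.58), and Car3 had a relative change of 0.05 that turned to −0.08 in edgeR and DESeq2. Of 16 measured genes of fibroblasts and preadipocytes, 3 were called higher (Ly6a, Icam1 and Cd34, which endothelial cells also express; 2 adjusted over the list alone), and the relative median was −0.41. In the relative values, limma called 2 fibroblast genes lower adjusted over the list alone and 0 over all genes, while DESeq2 called the fibroblast gene Cd55 and the adipocyte gene Adipoq lower (adjusted p = 0.0248 and 0.0306). Of 7 nuclear noncoding RNAs, a kind that ribosome capture depletes, limma called none in either scale, with a relative median of −0.76. Among them Malat1 was at a relative change of −1.90 (limma adjusted p = 0.450, DESeq2 adjusted p = 0.0358) and Neat1 at −0.04 (adjusted p = 0.975). Camera called these lists lower (adjusted p = 0.00539 for adipocyte, 0.0488 for fibroblast and 0.0241 for nuclear RNA), and none was called with an estimated correlation (adjusted p = 0.931 for each) or with the mitochondrial rRNA share as a covariate (0.994, 0.826 and 0.415, the adipocyte list then on the other side of 0). The nuclear call was lost with quantile normalisation (0.212) and the replicate block (0.350), the adipocyte call with that block (0.0536), and the fibroblast call with quantile normalisation (0.159), at a mean CPM of at least 5 (0.0631) and with the adipocyte covariate (0.170). The relative medians moved to −0.80 without WT replicate 4 and −0.77 without KO replicate 1 for adipocyte genes, to −0.76 without WT replicate 4 and −0.26 without WT replicate 2 for fibroblast genes, and to −1.20 without KO replicate 1 and −0.35 without KO replicate 5 for nuclear RNA. The adipocyte call was lost without WT replicate 2 (adjusted p = 0.117) or KO replicate 5 (0.0588). The nuclear call was lost without WT replicate 2 (0.0827), WT replicate 3 (0.0599), KO replicate 4 (0.0757) or KO replicate 5 (0.400), and the fibroblast call was lost without WT replicate 1 (0.0682), 2 (0.235) or 3 (0.0627) or KO replicate 1 (0.189), 3 (0.0893) or 4 (0.140).

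Skeletal muscle genes were among the largest rises in the deposited CPM. By the rule for the largest changes the 10 higher genes were Ryr1, Myh8, Myh4, Nme1, Tnnt3, Depp1, Rchy1, Slitrk4, Kpna2 and Neb, with log2 fold changes from 3.02 (Neb) to 3.65 (Ryr1). Of these 10 limma called only Depp1 relative to the library medians. DESeq2 also called Ryr1 (2.92, adjusted p = 0.00113) and Neb (2.47, adjusted p = 0.00564). It gave no adjusted p for Myh8, Myh4, Nme1, Tnnt3, Rchy1, Slitrk4 and Kpna2, so it left them undecided. All 10 measured skeletal muscle genes were called higher in the deposited CPM (10 adjusted over the list alone), with a relative median of 2.06 and 5 called in the relative values adjusted over the list alone. Myh4, a fast myosin heavy chain gene, was at 30.5 ± 25.0 CPM in WT (n = 4) and 881 ± 1589 CPM in KO (n = 5), and Tnni2, Tnnt3 and Myh1 had relative changes of 2.71, 2.28 and 1.83. KO replicate 5 held the highest value of each of the 7 muscle genes named here (Ryr1, Myh8, Myh4, Tnnt3, Neb, Tnni2 and Myh1), and without it the list's relative median was 1.19. Camera gave an adjusted p = 8.93e-07, and the list was not called with an estimated correlation (adjusted p = 0.931), with the mitochondrial rRNA share as a covariate (0.0588) or with the endothelial covariate (0.245).

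Camera at the preset correlation called proteasome, lysosome, ribosome and vascular tone genes higher as groups in the deposited CPM. Of 31 proteasome subunit genes, 22 were called higher in the deposited CPM (25 adjusted over the list alone), with a relative median of 0.47. Psma7 went from 22.4 ± 14.5 CPM (SD, n = 4) to 89.0 ± 31.2 CPM (SD, n = 5; limma adjusted p = 0.00417), and Psmc6, Psmb4 and Psma3 had relative changes of 1.46, 0.97 and 1.15. Of 27 lysosome genes, 20 were called higher (23 adjusted over the list alone; relative median 0.52), including the proton pump genes Atp6v1a (23.2 ± 12.5 to 82.1 ± 13.4 CPM) and Atp6v1b2 and the hydrolase genes Lipa and Neu1. Of 73 cytosolic ribosomal protein genes, 37 were called higher (49 adjusted over the list alone; relative median 0.28), led by Rps26, Rpl27a, Rps14 and Rps4x. Of 16 genes of vascular tone and flow response, 13 were called higher (14 adjusted over the list alone; relative median 0.37). These included the flow-responsive transcription factor gene Klf2 (98.0 ± 57.2 to 294 ± 103 CPM), the natriuretic peptide receptor genes Npr1 and Npr3, and Calcrl. No member of these 4 lists was called in the relative values by limma, or by edgeR or DESeq2. DESeq2 gave no adjusted p for some members, among them Psmc6, Psma3, Lipa, Atp6v1b2, Rps26, Rpl27a and Calcrl. Camera gave adjusted p = 0.000783, 0.00317, 0.0152 and 0.00385 in this order, and none was called with an estimated correlation (adjusted p = 0.931 for each) or with the mitochondrial rRNA share as a covariate (0.232, 0.174, 0.994 and 0.168). With the endothelial list mean as a covariate the proteasome, lysosome and vascular tone calls were lost (0.760, 0.605 and 0.724) and the ribosome list was called lower (0.0425). That covariate was a mean of uncentred values and carried the shift of all genes, so these changes do not measure endothelial content. The ribosome call was lost with median centring (adjusted p = 0.0600), with the replicate block (0.210) and without WT replicate 1 or 2 or KO replicate 3, 4 or 5 (0.0757 to 0.194), and the lysosome call was lost without WT replicate 1 (0.0515). The ribosome median moved to 0.18 without WT replicate 1, and the lysosome median to 0.27 without WT replicate 1 and 0.28 without KO replicate 2.

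Camera called none of the lists for the integrated stress response, FOXO targets, redox genes, mitochondrial fusion and fission, and complex I, and fry called all 5 in the deposited CPM (adjusted p = 0.00652 to 0.0172) and none in the relative values. Of 28 integrated stress response genes, 14 were called higher in the deposited CPM (14 adjusted over the list alone), among them Ddit4, Gdf15, Cebpb and Cebpg, and Ddit4 alone rose in the relative values (camera adjusted p = 0.489 for the list). Of 31 FOXO targets, 11 were called higher (13 adjusted over the list alone; camera adjusted p = 0.399), led by Ccn1, Txnip, Cdkn1a and Klf2. Txnip, which binds thioredoxin, went from 245 ± 130 CPM (SD, n = 4) to 814 ± 227 CPM (SD, n = 5), with a relative change of 0.86 (limma adjusted p = 0.229). Of 25 NRF2 and antioxidant genes, 11 were called higher (12 adjusted over the list alone; camera adjusted p = 0.353), led by Prdx1, Abcc4, Gsr and Taldo1. Of 22 mitochondrial fusion and fission genes other than Mfn2, 7 were called higher (7 adjusted over the list alone; camera adjusted p = 0.476), led by Miga1, March5, Yme1l1 and Fis1. Of 35 nuclear complex I genes, 11 were called higher (11 adjusted over the list alone; camera adjusted p = 0.357), led by Ndufa2, Ndufc1, Ndufs7 and Ndufc2. The shares called higher in these lists were 50.0%, 35.5%, 44.0%, 31.8% and 31.4% in this order, against 32.0% of all genes.

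Endothelial lipid handling and angiogenic genes lay just outside the threshold of the list test in the deposited CPM, further outside with median centring (adjusted p = 0.287 and 0.105) and within it with quantile normalisation (0.00721 and 0.00365). Of 21 genes of fatty acid uptake and transfer, 11 were called higher in the deposited CPM (14 adjusted over the list alone; relative median 0.32; camera adjusted p = 0.0749). Gpihbp1, which carries lipoprotein lipase to the capillary lumen, went from 372 ± 145 CPM (SD, n = 4) to 1106 ± 427 CPM (SD, n = 5), with a relative change of 0.59 (limma adjusted p = 0.463), and Angptl4, Fabp5 and Cav1 had relative changes of 0.97, 0.52 and 0.38, with Angptl4 called by DESeq2 (adjusted p = 0.0465). Of 24 angiogenic and tip cell genes, 11 were called higher (19 adjusted over the list alone; relative median 0.27; camera adjusted p = 0.0522), led by Pdgfb, Kdr, Nrp2 and Flt1. Both lists were called without WT replicate 4 (adjusted p = 0.0123 for lipid handling and 0.00256 for angiogenesis), and the angiogenic list also without KO replicate 1 (0.00980) or KO replicate 2 (0.0218). With all libraries and an estimated correlation the adjusted p was 0.931 for each. The angiogenic relative median moved to 0.50 without WT replicate 4, 0.43 without KO replicate 2 and 0.085 without KO replicate 5, and the lipid handling median to 0.21 without WT replicate 3.

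Over the 54 lists tested, camera called 8 higher and 4 lower, and with median centring 7 higher and 4 lower. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance 1 way, called 48 lists in the deposited CPM and 0 in the relative values (lowest adjusted p = 0.216, 8 lists at an unadjusted p under 0.05). Exact permutation of the relative list means called 0 lists (lowest adjusted p = 0.214), with 6 at an unadjusted p under 0.05.

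**Figure D3:**
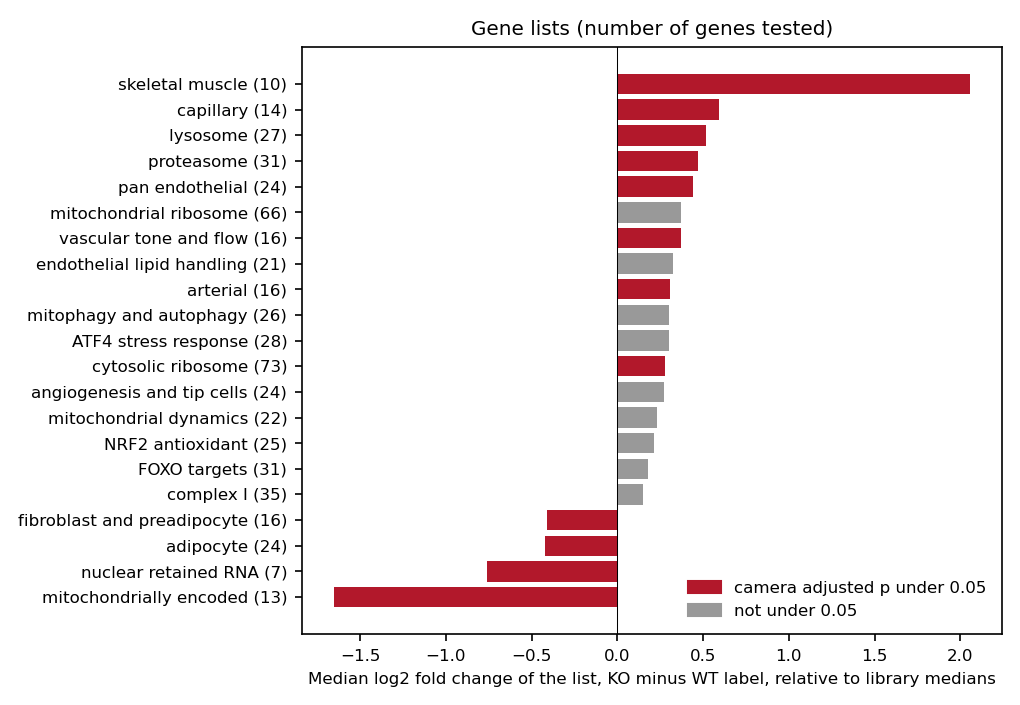
Median log2 fold change of the genes in each of 21 lists, KO minus WT label, relative to the library medians (horizontal axis), with the number of genes tested in brackets. Red bars mark lists with a camera adjusted p under 0.05 in the deposited CPM, from −1.65 for the mitochondrially encoded genes to 2.06 for skeletal muscle.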

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

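Of the values below, the share of Gm10800, Gm10801 and Gm21738 was chosen for testing only after it was seen. In 206 groups of 4 or 5 libraries the gap between 1 library and the rest was tested with Dixon's ratio. It passed the 95% critical value in 15, where chance alone gives about 1 in 20, or 10.3, and 5 of the 15 lay in KO replicate 5, 4 in WT replicate 4 and 3 in WT replicate 1.

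KO replicate 5 stood apart in skeletal muscle genes. Ryr1 was at 370.91 CPM in KO replicate 5 and between 37.2 and 70.3 CPM in the other libraries labelled KO. Myh8 was at 622.74 CPM there and between 25.3 and 59.5 CPM in the other KO libraries. Myh1 was at 553.54 CPM there and between 24.4 and 52.5 CPM in the others. In the same library Nrp2, a co-receptor for VEGF and semaphorins, was at 486.41 CPM, against 135 to 180 CPM in the other KO libraries. The predicted genes Gm10800, Gm10801 and Gm21738 took 0.104% of its reads, against 1.45% to 1.93% in the other KO libraries.

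WT replicate 4 stood apart in mitochondrial transcripts. Messenger RNA encoded by the mitochondrial genome took 1.55% of its reads and 0.284% to 0.443% in the other libraries labelled WT. Its mt-Co3 level was 172.95 CPM, against 35.2 to 43.5 CPM. Gdf15 was at 1.9 CPM in WT replicate 4 and at 0 in the other WT libraries, and Cebpb was at 0 CPM there and between 4.95 and 6.83 CPM in the others. In WT replicate 4, 1 read was 0.95 CPM, so the Gdf15 and Cebpb gaps rest on few reads.

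In WT replicate 1, Depp1 was at 6.3 CPM, against 20.0 to 22.6 CPM in the other libraries labelled WT. Rps4x was at 5.85 CPM in WT replicate 1 and between 17.9 and 20.2 CPM in the others, and Miga1 was at 5.85 CPM and between 0.79 and 1.05 CPM in the others. Slitrk4 was at 4.2 CPM in WT replicate 3 and at 0 in the other WT libraries. With 1 read at 0.45 CPM in WT replicate 1 and 0.53 CPM in WT replicate 3, the Miga1 and Slitrk4 gaps rest on few reads. Gm10800, Gm10801 and Gm21738 took 7.82% of the reads in WT replicate 3 and 0.548% to 1.40% in the other WT libraries. Neu1, a lysosomal sialidase gene, was at 23.07 CPM in KO replicate 1 and between 49.2 and 64.6 CPM in the other KO libraries.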

How the results depend on the processing

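Chosen only after the data were seen were all alternatives to the relative count, the mitochondrial rRNA and endothelial settings, leaving out WT replicate 4 with KO replicate 5, and exact permutation of list means. Across settings, values of single genes and lists kept direction and side of the threshold 2064 times, lost the call 779 times, gained it 31 times and turned 22 times. A gene without an adjusted p in DESeq2 counted as not called. The counts of genes and lists and the Mfn2 fold change stayed alike 56 times, moved 39 times and turned 4 times. Where no cause is named, the cause was not tested.

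The count of 3804 genes changed in the deposited CPM went to 9 with quantile normalisation, 13 with median centring, 26 with the mitochondrial rRNAs left out, 5 in edgeR and 155 in DESeq2. These settings remove the shift of the median by construction, wholly or in part. It was 1940 with the replicate number as a block, 733 with the adipocyte covariate, 22 with the mitochondrial rRNA covariate and 0 with the endothelial covariate. In these fits of genes and lists the endothelial covariate was a mean of uncentred values, so it carried the shift itself. With it the median log2 fold change of all genes was 0.30. The count of 0 therefore does not show that endothelial content accounts for the calls. Leaving out 1 library gave 1103 (WT replicate 1) to 5930 (WT replicate 4), with 1808 without WT replicate 3 and 1700, 2106 and 1838 without KO replicate 3, 4 and 5. The Mfn2 fold change turned to −0.17 with quantile normalisation and edgeR and to −0.16 with median centring and DESeq2, and ran from 0.54 (without KO replicate 1) to 1.05 (without WT replicate 2), with 0.13 under the adipocyte covariate and 0.23 with the mitochondrial rRNAs left out.

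The relative count of 13 genes was 5 in edgeR, 155 in DESeq2, 4 with a pseudocount of 0.5, 5 at a mean CPM of at least 5 and 63 with array weights. It was 38 with the block, 3 with the adipocyte covariate, 1 with the mitochondrial rRNA covariate and 6 without WT replicate 4 and KO replicate 5. It was 0 in limma without trend (1245 genes at an unadjusted p under 0.05) and with the endothelial covariate (809, or 1032 in the deposited CPM). Leaving out 1 library gave 0 (WT replicate 1; 1239 unadjusted) to 127 (KO replicate 1), with 1 without WT replicate 3 or KO replicate 3, 5 without WT replicate 4 and 4 without KO replicate 4. Of the 13, quantile normalisation shared 9, edgeR 5 and DESeq2 11. DESeq2 gave no adjusted p for Rprl3 and A130071D04Rik.

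The 12 lists called by camera were 1 with the mitochondrial rRNA covariate, 4 with the endothelial covariate, 0 with an estimated correlation (1 at an unadjusted p under 0.05), 48 in fry and 0 by exact permutation (6 unadjusted). Leaving out 1 library gave 7 (WT replicate 2) to 19 (WT replicate 4). With the mitochondrial rRNA covariate the direction turned for the adipocyte (adjusted p = 0.994), angiogenic (0.920) and complex I (0.920) lists. With the endothelial covariate it turned for the endothelial (0.259), capillary (0.764), adipocyte (0.405), ribosome (0.0425), nuclear RNA (0.764), arterial (0.445), angiogenic (0.137) and complex I (0.275) lists, for the endothelial list by construction. That covariate also turned Npr3 to −0.070, Ly6a to −0.35, Cd34 to −0.29, Fis1 to −0.25 and Flt1 to −0.14. The mitochondrial ribosome list turned without WT replicate 4 and KO replicate 5 (0.818). Neat1 turned to −0.038 with median centring and −0.19 in edgeR and DESeq2, and Car3 to −0.081 and −0.076.

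The filter on low values removed 0 genes, so dropping it tests nothing. The same replicate number did not link libraries: centred values of the 4 same-number pairs correlated at 0.03, −0.02, −0.04 and 0.04 across genes, and KO replicate 5 has no partner in the block. Genes at 0 numbered 683 in WT replicate 4, the library with the fewest reads, and 837 and 786 in WT replicates 1 and 3. The median gene had 14 to 26 reads in the libraries labelled WT and 35 to 93 in those labelled KO, which limits the precision of single genes.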

Other observations

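The tests on the mitochondrial rRNA share, on RNA from other cell types, on scaling and on splits by the count of higher genes were chosen only after the result was seen.

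Genes of mitophagy and autophagy and of the mitochondrial ribosome lay higher in the libraries labelled KO in the deposited CPM, without a camera call for either list. Fry called both there (adjusted p = 0.00685 and 0.00652), as it did 48 of the 54 lists, and it called 0 lists in the relative values. Of all genes 32.0% were called higher in the deposited CPM, against 46.2% and 36.4% of these lists. Of 26 genes of mitophagy and autophagy, 12 were called higher (18 adjusted over the list alone), with a median of 0.30 relative to the library medians, or 0.17 without WT replicate 3. Gabarapl2, which helps to form autophagosomes, went from 13.7 ± 8.40 CPM (SD, n = 4) to 47.8 ± 13.0 CPM (SD, n = 5), with a log2 fold change of 1.87 (limma adjusted p = 0.00880). The mitophagy receptor gene Bnip3l, the kinase gene Pink1 and the autophagy kinase gene Ulk2 had log2 fold changes of 1.77, 1.61 and 1.86. The list had a camera adjusted p = 0.150 (0.931 with an estimated correlation) and an exact permutation p = 0.00794 for its relative mean, or 0.214 adjusted over 54 lists. Of 66 genes of the mitochondrial ribosome, 24 were called higher (29 adjusted over the list alone), led by Mrpl11, Mrpl9, Mrpl21 and Mrps12 with log2 fold changes of 2.58, 1.96, 2.16 and 2.39. That list had a relative median of 0.37 and a camera adjusted p = 0.248, which became 0.0412 with median centring, and 0.931 with an estimated correlation.

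Small nuclear RNAs and lymphocyte genes lay lower relative to the library medians, and none was called. The 27 small nuclear RNA genes had a relative median of −0.98 (exact permutation p = 0.143 for their mean, n = 4 and 5), and the 63 long intergenic RNAs had −0.35. The lymphocyte genes Ighm, Cd37, Igkc and Ptprc had relative changes of −1.90, −1.75, −1.58 and −0.85 (lowest adjusted p = 0.232). Of the brown adipocyte genes, Ucp1 and Cidea had relative changes of −1.21 and −1.35, Ppargc1a had −0.54 and Ppara had 0.27. The 4 Y-linked genes measured had a relative median of 0.33, and 2 of them were called higher in the deposited CPM.

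The first pattern weighed is that nearly all genes lay higher in the libraries labelled KO in the deposited CPM. Only 1 of 100 drawn splits of the 9 libraries, the real one, called as many genes, with 3804 against at most 1991. Chance is argued against but not excluded, since 1 in 100 is the smallest share these draws can give. That 1991 came from the 4 libraries with the largest share of mitochondrial rRNA (WT replicates 1 to 3 and KO replicate 2) and points to a structure along that share. With each library thinned to 1034753 reads, 3261 genes were called higher, against 3780, which argues against a difference in total reads alone. CPM are already scaled to the total, so thinning could do little to the median shift. It also left the share of nuclear protein-coding reads unequal, from 22.5% in WT replicate 1 to 76.5% in KO replicate 5. Fewer reads of nuclear genes in the WT libraries were therefore not tested as a cause. Mitochondrial rRNA as the whole cause is argued against, since without it the library medians still differed by 0.44 (exact permutation p = 0.00794), while a median fold change of 0.60, down from 1.10, keeps its part open. Within nuclear protein-coding reads alone the median was 0.41, consistent with reads outside them as a main source, yet library medians still differed by 0.25 (exact permutation p = 0.00794), and an effect of Mfn2 loss stays open and untested.

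The second pattern is that endothelial genes lay higher and adipocyte genes lower relative to the library medians, a difference of 0.86 between the list medians that was 0.73 in edgeR with TMM and 1.02 with quantile normalisation, the only scaling tried that is not 1 factor per library, which argues against scaling that varies with level. Less RNA of every other cell type alike was weighed by shuffling genes between 7 lists of other cell types (permutation p = 1e-05, the smallest the permutations can give). Medians were 2.06 for skeletal muscle, 0.30 for mural, −0.48 for 15 fibroblast and −0.43 for 21 adipocyte genes, after leaving out genes on an endothelial list or on more than 1 of these lists. Genes of a list vary together in the same libraries, so that p does not measure the spread between libraries and cannot decide the question. Over libraries the relative muscle mean had an exact permutation p = 0.0873, with 4.28 in KO replicate 5 and −1.34 in KO replicate 4. With muscle set apart the remaining 6 lists were not shown to differ (permutation p = 0.115 over genes, with the same limit), and their 75 genes had a median of −0.39. Less RNA carried over from other cells, which the capture of tagged ribosomes should remove, therefore stays open. Abundant genes ran from 0.45 for Fabp4 to −1.07 for Pck1 and −0.83 for Col3a1. Which cells gave these RNAs was not tested, so they do not decide the question. The share of mitochondrial rRNA and the label cannot be told apart here: with that share as a covariate the difference between the list medians was 0.084, and the difference per library went from 0.95 to 0.13 (SE 0.560, 95% interval −1.24 to 1.50), too wide to exclude either. Endothelial minus adipocyte values were 0.05 ± 0.71 in WT and 1.00 ± 0.83 in KO (SD, n = 4 and 5; exact permutation p = 0.103). WT replicate 4, the WT library with a mitochondrial rRNA share in the KO range, was at 1.11, near the KO mean, and WT replicates 1 to 3 were at −0.22, −0.26 and −0.43. KO replicate 1 was at −0.32 with a low share. A single matched WT library cannot decide between share and label, and a change within endothelial cells stays open and untested.

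In these lists chance cannot be excluded: 21 of 100 drawn splits called at least the 12 lists of the real one, and the highest other split called 21.

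The third pattern is the rise of Depp1, Ddit4, Rhob and Selenok relative to the library medians. Only 1 of 100 drawn splits, the real one, called as many genes higher in the relative values, 4 against at most 2. The same held for either direction, 13 against at most 2. Chance is argued against but not excluded, since 1 in 100 is the smallest share these draws can give. The 13 also became 0 in limma without trend or without WT replicate 1, and 1 without WT replicate 3 or KO replicate 3. The median change of the 4 genes was 1.82 without KO replicate 5 and 1.86 with it, so the rise did not rest on that library. All 5 KO libraries lay above all 4 WT libraries for these genes, so leaving out 1 could change little. Muscle RNA in the other KO libraries was not tested. Their relative muscle means were 1.05, 0.69, 0.60 and −1.34 in KO replicates 1 to 4, against at most −0.37 in WT. A larger endothelial share as the whole cause is argued against. With the endothelial list mean as a covariate the median change of the 4 genes was 1.62. The calls ended there, with Depp1 going from 2.26 (SE 0.331, limma adjusted p = 0.00944) to 1.95 (SE 0.370, adjusted p = 0.221) as the change shrank and its error grew, so a part for that share and an effect of Mfn2 loss both stay open.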
